A study of Homo sapiens with 4 samples.

How the data were processed

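Gene expression was measured in U937 cells, a human cell line derived from a lymphoma, on Affymetrix HG-U133 set A arrays, with 1 array for each of 4 RNA samples. Per the labels' protocols, total RNA was isolated on spin columns, freed of DNA with DNase, copied into double-stranded cDNA with a one-cycle kit and transcribed into biotin-labelled cRNA for hybridisation. The deposited values are 1 intensity on a linear scale for each of 22283 probe sets on each array, taken from the series' value table. The software that summarised probes into these signals is not given in the sources used here. The values themselves show scaling between arrays, since the mean of each array after trimming 2% of the values at each end was 499.9 on all 4 arrays. Groups and replicate numbers came from the sample titles, which give 2 controls and 2 heated samples.

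The array medians differed by a factor of at most 1.04, within the 10% tolerance, so the deposited intensity values were used without further normalisation. The 68 control probe sets were left out of the tests. Signals were converted to log2(signal + 7.56), where 7.56 is the 10th percentile of all values, so a fold change of a dim probe set is understated. Probe sets were tested if their mean over the 4 arrays was at or above the 40th percentile of such means, which kept 13329 of them, from a mean near a signal of 52.9 upward. The genes of a probe set came from the platform annotation, in which 19065 probe sets name 1 gene, 1043 name several and 2107 name none in the table used here. Of the probe sets with 1 gene, 19053 had an Entrez identifier in the RefSeq gene table and 0 symbols had to be updated. No gene was named from a probe set with several genes. Where a gene had more than 1 tested probe set, the one with the highest mean stood for it, which gave 7852 genes. Chromosome positions from the RefSeq table were used only to find the neighbours of raised genes.

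Heated and control arrays were compared with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with an intensity trend, without a replicate block. All limma p-values are two-sided and were adjusted by the Benjamini-Hochberg method over the 13329 probe sets, with a threshold of 0.05. The fit had 2 residual degrees of freedom and borrowed 9.02 prior degrees of freedom from the other probe sets. A second count took probe sets at least 1.5-fold apart in the same direction in all 4 pairs of a control and a heated array, and the same count was made for the other 2 ways of splitting the 4 arrays into 2 and 2.

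Gene lists of 32 groups were written before the data were examined, as were the design, the named gene rule and most of the alternative settings. They cover the heat shock families, co-chaperones and heat shock factors, other stress responses, cell death, the cell cycle and histones, inflammation and interferon, metabolism, ribosomal proteins and translation, splicing, DNA repair, and markers of myeloid, T and NK, B, erythroid and epithelial or fibroblast cells. The 29 lists with at least 5 measured genes were tested with limma's camera with a preset inter-gene correlation of 0.01, adjusted over the lists. The test was repeated with an estimated correlation, and fry was used for the direction of each list on its own. Counts of changed members are given with the adjustment over all probe sets and with the adjustment over the list alone.

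The genes named in the text are those past the threshold whose heated arrays both lay above, or both below, both control arrays, namely the 15 with the largest rise and the 10 with the largest fall. To these were added up to 3 genes of each list with the largest change in either direction, whatever their p, and all genes that passed in the heat shock and co-chaperone lists. HSF1, HSPA8, GAPDH and ACTB were set as reference genes. HSPA8 is not reported, since no tested probe set named it alone. Any other gene named was chosen after its values were seen, and this is said where it appears.

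The fit was tested on simulated data, with 10 sets of 13329 probe sets in which 200 were changed. Variances were drawn around the intensity trend fitted here, and noise was drawn independently for each probe set. The rates below therefore hold only for data that follow that trend. With the intensity trend, 12.1% of the probe sets changed 1.5-fold were recovered, 50.2% of those changed 2-fold and 84.6% of those changed 4-fold, and 5.38% of the calls were false. The fold rule recovered 85.1% of the probe sets changed 2-fold or more, and passed a mean of 110.1 unchanged ones. A list shifted by 0.3 on the log2 scale was called in 100% of the sets, with a mean of 0.1 unshifted lists called per set. Since the simulated genes were independent, these list rates do not show how camera behaves for lists of correlated genes.

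The alternatives changed the pseudocount, the filter on dim probe sets, the normalisation between arrays, the variance model, the replicate block, the probe sets that can cross-hybridise, the fold threshold, the inter-gene correlation and the probe set that stands for a gene, and left out each array in turn. Cyclic loess, a 1.5-fold minimum beside the adjusted p, and 75th percentile centring for the lists were added after the data were seen.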

Results

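U937, a human lymphoma line whose cells resemble monocytes, was used to ask which genes respond to mild heat. Of the 4 RNA samples, 2 came from untreated cells kept at 37 °C and 2 from cells held at 41 °C for 30 min and then returned to 37 °C for 3 h. Each sample was hybridised to 1 array of 22283 probe sets. The median signal was 102.8 and 106.1 on the control arrays and 101.7 and 103.5 on the heated arrays. The 3' to 5' signal ratio of the GAPDH control probe sets, a measure of RNA integrity, was 0.923 and 0.971 in control cells and 0.991 and 1.01 in heated cells. Across the 13329 tested probe sets, which are not independent replicates, the Pearson correlation was 0.983 between the control arrays, 0.975 between the heated arrays and 0.965 to 0.967 between groups. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

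The strongest responses to mild hyperthermia were those of heat shock and chaperone genes. HSPA6, a stress-inducible member of the HSP70 family of chaperones, rose 86.1-fold, from a signal of 125 ± 14.3 in control cells to 11336 ± 602 in heated cells (SD, n = 2 per group here and throughout). BAG3, a co-chaperone of HSP70, rose 21.4-fold from 366 ± 37.1 to 7971 ± 919. DNAJB1, a J-domain partner of HSP70, rose 18.6-fold from 1167 ± 103 to 21835 ± 1477. SERPINH1, a collagen chaperone of the endoplasmic reticulum, rose from 10.2 ± 5.26 to 367 ± 82.1. The log2 changes were 6.43 (SE 0.14) for HSPA6, 4.42 (SE 0.14) for BAG3, 4.22 (SE 0.12) for DNAJB1 and 4.41 (SE 0.41) for SERPINH1. The control signals of SERPINH1 lie near the pseudocount, so the size of its change depends on it, with 4.76 for a pseudocount of 3.78 and 3.91 for one of 15.1. The limma adjusted p was 7.4e-10, 7.5e-09, 3.4e-09 and 1.6e-04 for these genes in turn. A second probe set of HSPA6 rose by 6.35 on the log2 scale. Alongside these, 3 probe sets that each match more than 1 gene of the HSP70 family also rose. The one that matches 3 genes went from 842 ± 22.5 to 28287 ± 3059 (adjusted p = 9.2e-10). The other 2, which match 2 genes each, went from 860 ± 68.7 to 23061 ± 495 (9.2e-10) and from 491 ± 90.7 to 10218 ± 1063 (1.6e-08).

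**Figure D1:**
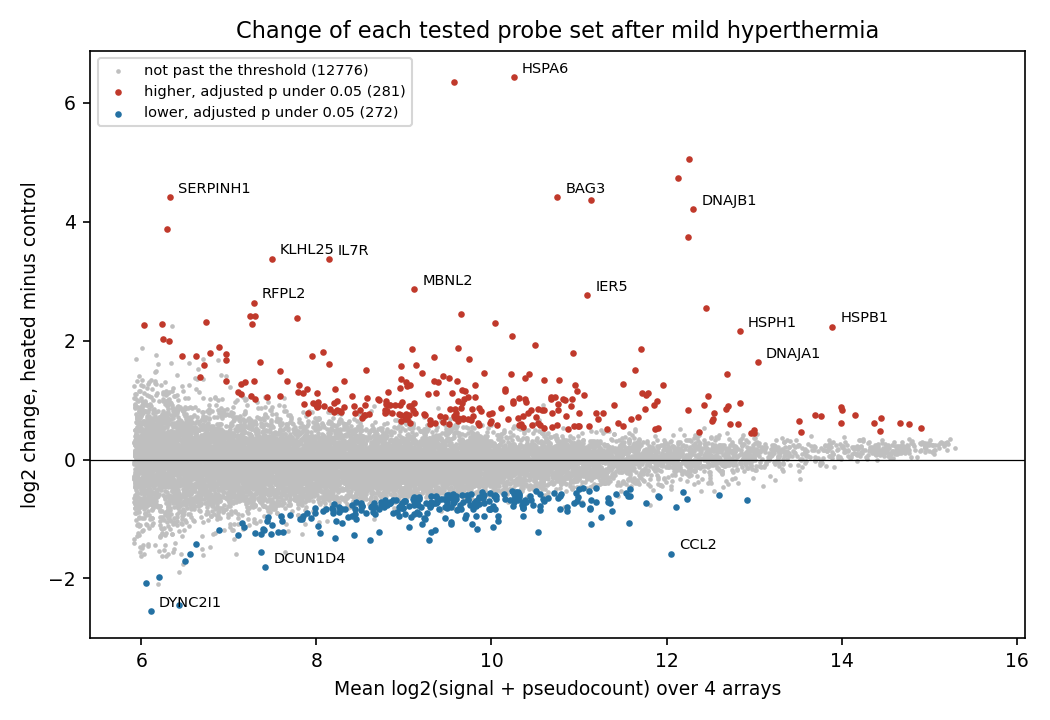
Log2 change (heated minus control) of each of the 13329 tested probe sets against its mean log2 signal over the 4 arrays, with the 281 raised probe sets in red, the 272 lowered ones in blue and the rest in grey. HSPA6 lies highest at 6.43, and the lowest point past the threshold is DYNC2I1 at -2.55.

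Mild hyperthermia raised 281 probe sets and lowered 272, together 4.15% of the 13329 tested. Counted once per gene, 174 genes rose and 175 fell. The rises were the larger changes, with 124 raised and 49 lowered probe sets differing at least 2-fold, and 30 raised and 3 lowered probe sets at least 4-fold. The median log2 change was 0.93 among raised and -0.77 among lowered probe sets. Of the changed genes, 144 had another tested probe set, and in 60 of them another one was also called the same way, with 0 called the opposite way. Of the 221 other probe sets of changed genes, 91.9% had the same sign, against 66.8% for genes that were not called. The size rule found 551 probe sets at least 1.5-fold apart in all 4 array pairs (289 higher and 262 lower in heated cells), and 350 of these also passed limma. The other 2 splits of the arrays gave 93 and 84 by the size rule, and 0 each by limma, with 156 and 259 at an unadjusted p under 0.05 against 2500 for the real split. Each of these splits puts 1 control and 1 heated array in each group. The heat response then adds to the spread within groups, so their limma counts do not measure what chance gives. In 6548 probe sets (49.1%) the groups did not overlap, where chance gives 33.3%. The share of calls that were rises was 50.8% in the deposited scaling, 60.5% after quantile normalisation, 64.0% after cyclic loess and 66.2% after centring on the 75th percentile. Of the 87 called genes and probe sets named in the text, 72 lost their call without the intensity trend and 44 without the filter on dim probe sets. The count of limma calls was 199 without that filter and 27 without that trend. It was 200 (155 up and 45 down) without control array 1, 264 (190 and 74) without control array 2, 947 (337 and 610) without heated array 1 and 818 (318 and 500) without heated array 2. Rises were thus 77.5% and 72.0% of the calls without a control array, and 35.6% and 38.9% without a heated array.

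Members of every chaperone family examined rose, and none of their measured members fell with the adjustment over all probe sets. In the HSP70 list, 5 of 8 measured genes rose and 3 did not pass, and 5 rose and 0 fell when adjusted over the list alone. Besides HSPA6, these were HSPA1L (58.3 ± 3.24 to 345 ± 51.3), HSPA4L (log2 change 1.88), HSPA13 (1.15) and HSPA4 (0.78). The 1 other tested probe set of HSPA13 was not called, while 2 of the 3 others of HSPA4 were. In the HSP90 and HSP110 list, 3 of 6 rose and 3 did not pass, also 3 when adjusted over the list alone. These were HSPH1, an HSP110 that went from 3540 ± 1188 to 15712 ± 4040, and the cytosolic HSP90 genes HSP90AA1 (0.62, SE 0.10) and HSP90AB1 (0.48, SE 0.11). In the chaperonin list, 2 of 10 rose, namely HSPE1 (0.75) and HSPD1 (0.53), the mitochondrial chaperonin pair. The other 8 did not pass, although 5 rose and 0 fell when adjusted over the list alone, and all 10 had a higher mean in heated cells. In the co-chaperone list, 7 of 20 rose and 13 did not pass, with 10 rising and 2 falling when adjusted over the list alone. Besides BAG3 and SERPINH1 these were FKBP4 (1.26), CHORDC1 (1.05), CACYBP (0.96), STIP1 (0.84) and CDC37 (0.59). Camera called the HSP70 (adjusted p = 3.0e-07), co-chaperone (2.1e-06), chaperonin (2.6e-05) and HSP90 and HSP110 (0.0028) lists upward. For each of these 4 lists it gave an adjusted p = 0.38 with an estimated correlation. Of all 29 lists tested, camera called 11 upward and 0 downward with its preset correlation, and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05 upward (HSP70 and co-chaperones). By fry, 2 lists were called upward, HSP70 and HSP90 and HSP110 (adjusted p = 0.013 each).

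J-domain proteins and small heat shock proteins showed strong rises in a few members. In the HSP40 list, 5 of 26 measured genes rose and 21 did not pass, with 5 rising and 1 falling when adjusted over the list alone. After DNAJB1 the largest were DNAJA1, which went from 4764 ± 326 to 14908 ± 558, and DNAJB4 (log2 change 1.32), followed by DNAJB9 (0.78) and DNAJB6 (0.68). The 1 other tested probe set each of DNAJB4 and DNAJB9 was not called, while those of DNAJB1 and DNAJA1 were. The list as a whole was not called by camera (adjusted p = 0.075), but it was called without control array 1 (0.019) or heated array 1 (0.033). Of the 4 measured small heat shock proteins, HSPB1 rose from 7018 ± 311 to 33098 ± 1264, and CRYAB, an alpha-crystallin, from 24.4 ± 16.5 to 136 ± 14.5. The other 2 did not pass, although 1 gene of this list fell when adjusted over the list alone. The mean control signal of CRYAB lies below 52.9, the lowest mean tested, so the size of its rise depends on the pseudocount. The heat shock factor list had 3 measured genes, of which 0 passed in limma, with 0 at an unadjusted p under 0.05. HSF1, the main transcription factor of the heat shock response, differed by -0.37 (SE 0.19, adjusted p = 0.35). A second probe set of HSF1 differed by -0.04 (SE 0.26).

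In these chaperone lists, some calls were lost when 1 array was left out, while every change kept its direction. Without control array 1, CRYAB, DNAJB4, DNAJB9, DNAJB6, HSP90AA1, CDC37, HSPD1 and HSP90AB1 had an adjusted p between 0.074 and 0.27. Without control array 2, DNAJB4, DNAJB9, DNAJB6, CDC37, HSPD1 and HSP90AB1 lay between 0.060 and 0.36. Without heated array 1, DNAJB4 had 0.061 and HSP90AB1 0.059, and without heated array 2, CDC37 had 0.082. HSPD1 and HSP90AB1 had an adjusted p of 0.067 and 0.15 after quantile normalisation, and of 0.054 and 0.11 after cyclic loess. By the probe set that stood for each gene, HSPA6, BAG3, SERPINH1, DNAJB1, HSPA1L, HSPA4L and HSPB1 were called without the intensity trend. By that probe set the other called genes of these lists were not. Other probe sets of HSPH1 (log2 change 2.54, limma adjusted p = 0.017) and DNAJA1 (1.87, 0.032) were called without that trend.

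**Figure D2:**
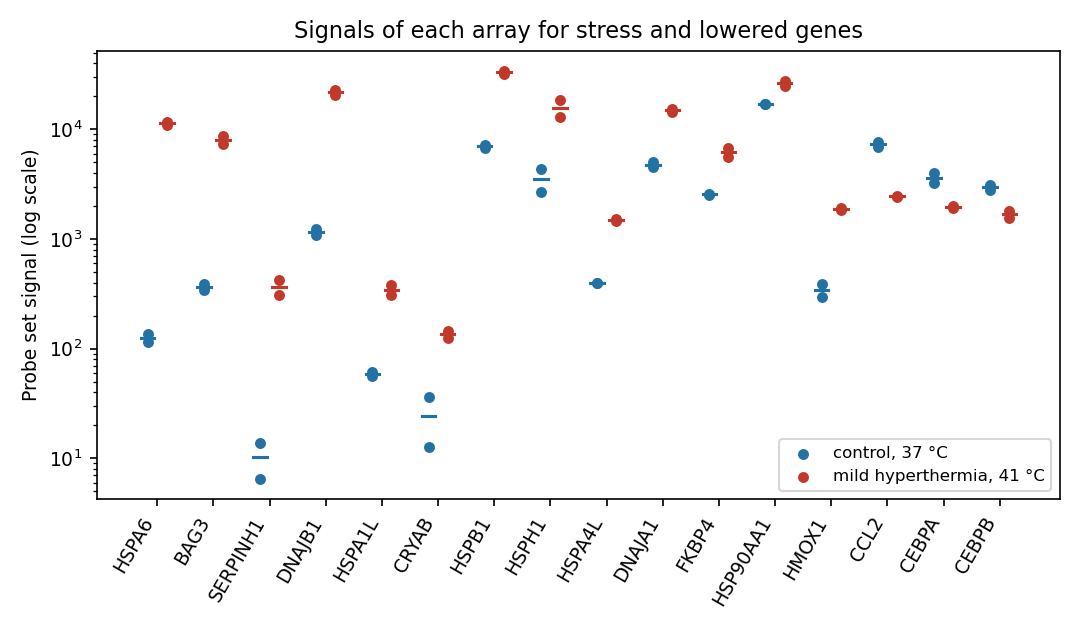
Probe set signal (log scale) of each of the 4 arrays for 16 genes, with control cells in blue, heated cells in red and a bar at each group's mean. The signal of HSPA6 lies near 125 in control cells and 11336 in heated cells, and that of CCL2 near 7357 and 2447.

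Outside the heat shock lists, the genes with the largest rise had varied known roles. IL7R, the receptor chain for interleukin 7, rose from 82.2 ± 25.3 to 946 ± 384, and IER5, an immediate early response gene, from 831 ± 83.2 to 5739 ± 1146. MBNL2, a regulator of alternative splicing, rose from 198 ± 15.1 to 1498 ± 83.1, and 2 further probe sets of this gene rose by 2.39 and 1.67 on the log2 scale. HMOX1, the heme-degrading enzyme heme oxygenase 1, rose from 340 ± 63.5 to 1867 ± 62.6, and DOK2, a docking protein of blood cell signalling, from 469 ± 73.0 to 2338 ± 472. KLHL25, an adaptor of cullin ubiquitin ligases, had a log2 change of 3.38 (SE 0.40), or 4.17 without control array 1 and 2.59 without control array 2. A probe set with no gene in the table, singled out after its values were seen, rose by 3.87 from control signals near the pseudocount, so the size of its rise depends on it. RFPL2 (2.64, SE 0.26), COL2A1 (2.31, SE 0.37) and ARHGEF16 (2.28, SE 0.46) rose from mean signals of at most 55.1. Those of COL2A1 and ARHGEF16 lie below 52.9, the lowest mean tested, so the size of their rise depends on the pseudocount. Without the intensity trend, IL7R, DOK2, KLHL25, COL2A1 and ARHGEF16 were not called. ARHGEF16 had an adjusted p of 0.058 without control array 1.

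Apart from CCL2, the genes with the largest fall had mean control signals from 129 to 534. CCL2, a chemokine that attracts monocytes, fell from 7357 ± 544 to 2447 ± 16.4 (log2 change -1.58, SE 0.11, adjusted p = 1.9e-05). Its limma adjusted p was 0.060 without the intensity trend, where DCUN1D4 was the only lowered gene called. DYNC2I1, a subunit of the dynein of cilia, fell from 159 ± 0.691 to 22.8 ± 14.7, and PYCR3, an enzyme of proline synthesis, from 129 ± 6.91 to 28.0 ± 20.7. DCUN1D4, a cullin neddylation factor, fell from 312 ± 3.66 to 83.8 ± 6.04, while its other 2 probe sets differed by -0.92 and -0.47 and were not called. The rest were the homeobox gene HMBOX1 (log2 change -1.70), the vitamin B12 processing gene MMACHC (-1.59), UBL3 (-1.27), the semaphorin SEMA3G (-1.27), the peptidyl-prolyl isomerase gene FKBP11 (-1.26) and the LIM-domain gene LMO1 (-1.22). A second probe set of UBL3 differed by -0.02. The mean heated signals of DYNC2I1, PYCR3, HMBOX1 and MMACHC lie below 52.9, the lowest mean tested, so the size of their change depends on the pseudocount. Without control array 1, HMBOX1, MMACHC, SEMA3G, FKBP11 and LMO1 had an adjusted p between 0.12 and 0.29. Without control array 2, these and UBL3 lay between 0.067 and 0.28, and without heated array 1, MMACHC had 0.050, still above the threshold. PYCR3 had a log2 change of -1.44 without heated array 1 and -2.71 without heated array 2. It had an adjusted p of 0.051 with a pseudocount of 3.78, 0.056 without _s_at and _x_at probe sets, 0.053 after quantile normalisation and 0.052 after cyclic loess and after centring on the 75th percentile, and MMACHC 0.052 after the last 2 of these.

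Immediate early genes moved in both directions. Of 25 measured, 4 rose, 2 fell and 19 did not pass, with 6 rising and 5 falling when adjusted over the list alone (camera adjusted p = 0.30). The list's median change was -0.09 and its mean 0.10. IER5 and the phosphatase gene DUSP1 (log2 change 1.33) rose, and EGR1 differed by -1.08 without passing (adjusted p = 0.055). The other 4 that passed, chosen after their values were seen, were IER3 (0.95), BTG1 (0.90), MYC (-0.68) and DUSP2 (-0.96). Without control array 1, IER3 and DUSP2 had an adjusted p of 0.096 and 0.19, and without control array 2, IER3, DUSP2 and MYC had 0.086, 0.35 and 0.22. Without heated array 2, MYC had 0.11 and DUSP2 0.074. DUSP2 had 0.050 (above the threshold) with a pseudocount of 3.78, 0.052 without _s_at and _x_at probe sets, 0.069 after quantile normalisation, 0.068 after cyclic loess and 0.064 after centring on the 75th percentile, and MYC 0.062 after that centring.

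Among p53 targets, 2 of 12 measured rose and 10 did not pass, with 3 rising and 0 falling when adjusted over the list alone (camera adjusted p = 0.18). These were CDKN1A, a cell cycle inhibitor (54.1 ± 24.4 to 201 ± 57.9), and PMAIP1, a pro-apoptotic BH3-only gene (877 ± 229 to 1680 ± 51.0). The 1 other tested probe set of PMAIP1 was not called. PMAIP1 was also the 1 gene of 21 that rose among pro-apoptotic genes, where 0 fell and 20 did not pass (1 and 0 when adjusted over the list alone, camera adjusted p = 0.13). BAG3 was the 1 of 12 that rose among anti-apoptotic genes, where 0 fell and 11 did not pass. Adjusted over the list alone 1 rose and 3 fell (camera adjusted p = 0.58). BCL2 differed by -0.61 (adjusted p = 0.084) and FAS by 0.70 (0.092). CDKN1A had an adjusted p of 0.078 without control array 2 and 0.070 without heated array 1, and PMAIP1 had 0.11 without control array 1.

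Cell cycle genes changed in small numbers. In the G1/S and DNA replication list, CDC6, a replication licensing factor, rose (log2 change 0.99), the cyclins CCNE1 (-0.91) and CCND2 (-0.70) fell, and 31 of 34 did not pass. The counts were the same when adjusted over the list alone, with 1 up and 2 down (camera adjusted p = 0.18). In the G2/M and mitosis list, 3 of 39 fell, 0 rose and 36 did not pass, with 1 rising and 4 falling when adjusted over the list alone (camera adjusted p = 0.21). The genes that fell were the spindle checkpoint kinase gene BUB1B (-0.80), CCNF (-0.77) and, chosen after its values were seen, KIF2C (-0.53). The 2 other tested probe sets of CCND2, and the 1 other each of CCNF and KIF2C, were not called, while the 1 other of CDC6 was. Of 8 measured replication-dependent histone genes and 26 DNA repair genes, 0 passed in limma under either adjustment. At an unadjusted p under 0.05 there were 0 histone and 2 DNA repair genes, and camera gave 0.36 and 0.26. Without control array 1, CCNE1, CCND2, CCNF and KIF2C had an adjusted p between 0.076 and 0.32. Without control array 2 these and BUB1B lay between 0.096 and 0.23. CCNF had 0.086 without heated array 2 and KIF2C 0.054 without heated array 1. CCNF also had 0.052 without _s_at and _x_at probe sets, 0.073 after quantile normalisation, 0.077 after cyclic loess and 0.060 after centring on the 75th percentile, and KIF2C had 0.051 and 0.067 after the last 2 of these.

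Inflammatory genes showed few changes beside the fall of CCL2. In the NF-kappaB and inflammatory list, IL1B, the interleukin 1 beta gene, rose from 179 ± 30.5 to 342 ± 15.4, CCL2 fell and 17 of 19 did not pass. Adjusted over the list alone, 1 rose and 1 fell (camera adjusted p = 0.78). The 1 other tested probe set of IL1B was not called. Of 18 measured interferon response genes, 0 passed in limma under either adjustment or at an unadjusted p under 0.05 (camera adjusted p = 0.23). IL1B had an adjusted p of 0.28 without control array 1, 0.055 without control array 2 and 0.061 without heated array 2.

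Among monocyte and myeloid markers, both genes of 20 that passed fell, and they were transcription factors of myeloid differentiation. CEBPA fell from 3619 ± 576 to 1963 ± 71.3 and CEBPB from 2959 ± 245 to 1682 ± 191, with log2 changes of -0.87 (SE 0.14) and -0.81 (SE 0.13). The other 18 did not pass, and 0 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.57). Of all 20, 13 had a higher mean in heated cells and 7 a lower one. CEBPA had an adjusted p of 0.076 without control array 1 and CEBPB 0.057 without control array 2. Of the markers of other cell types, IL7R was the 1 of 5 measured T and NK cell markers that rose, with 4 not passing and 1 up and 0 down when adjusted over the list alone (camera adjusted p = 0.19). NKG7, another of these, differed by 0.18 (adjusted p = 0.47). Of 5 B cell markers and 6 epithelial and fibroblast markers, 0 passed in limma under either adjustment, 1 and 0 had an unadjusted p under 0.05, and camera gave 0.57 for each. Of 4 erythroid markers, 1 fell and 3 did not pass, also 1 when adjusted over the list alone. It was TFRC, the transferrin receptor (log2 change -0.54), which had an adjusted p of 0.11 without control array 1 and 0.23 without control array 2.

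In the cholesterol biosynthesis list, 3 of 17 measured genes fell, 0 rose and 14 did not pass, with 1 rising and 4 falling when adjusted over the list alone. The genes that fell were INSIG1, which retains the sterol sensor complex in the endoplasmic reticulum (2529 ± 476 to 1391 ± 260), the lanosterol synthase gene LSS (log2 change -0.71) and, chosen after its values were seen, the squalene epoxidase gene SQLE (-0.66). All 3 tested probe sets of INSIG1 fell. The 2 other tested probe sets of SQLE and the 1 other of LSS were not called. The list's median change was -0.24, and camera gave an adjusted p of 0.13, or 0.035 without control array 2. LSS and SQLE had an adjusted p of 0.15 and 0.28 without control array 1, and LSS and INSIG1 had 0.13 and 0.13 without control array 2.

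Other stress lists were called upward by camera with 2 or fewer called members each. In the endoplasmic reticulum stress list, DNAJB9 was the 1 of 27 that rose, with 0 falling, 26 not passing and 4 rising and 1 falling when adjusted over the list alone (camera adjusted p = 0.024). In the oxidative stress list, HMOX1 and the superoxide dismutase gene SOD1 (log2 change 0.46) rose and 18 of 20 did not pass, with 2 rising and 1 falling when adjusted over the list alone (0.043). In the ubiquitin and proteasome list, the polyubiquitin gene UBB (0.62) was the 1 of 31 that rose, with 0 falling and 30 not passing (1 and 0 when adjusted over the list alone, 0.043). In the glycolysis and hypoxia list, P4HA1, a collagen prolyl hydroxylase (0.95), was the 1 of 25 that rose, with 0 falling and 24 not passing (1 and 0 when adjusted over the list alone, 0.043). Of 7 metallothioneins, 0 passed in limma under either adjustment, with 2 at an unadjusted p under 0.05 (0.044). With an estimated correlation, the adjusted p = 0.42 for metallothioneins and the adjusted p = 0.38 for each of the other 4 lists. The calls of the ubiquitin, glycolysis and metallothionein lists were lost without any 1 of the 4 arrays (adjusted p between 0.054 and 0.18). That of the oxidative stress list was lost without control array 1 (0.11), control array 2 (0.058) or heated array 2 (0.095), and that of the endoplasmic reticulum list without control array 2 (0.16) or heated array 1 (0.085). The endoplasmic reticulum list was the only 1 of these 5 that kept its call under quantile normalisation (0.0498) and cyclic loess (0.046). SOD1 was not called without either control array or heated array 1 (adjusted p between 0.060 and 0.26) or after quantile normalisation (0.14), cyclic loess (0.089) or without _s_at and _x_at probe sets (0.051), and UBB was not without control array 1 (0.067).

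Ribosomal protein genes were slightly higher in heated cells in the deposited scaling, with a median log2 difference of 0.16 that turned to -0.05 after quantile normalisation and to -0.02 after cyclic loess. Of 41 measured, 0 passed in limma under either adjustment, with 7 at an unadjusted p under 0.05, and 40 had a higher mean in heated cells. Camera called the list upward (adjusted p = 1.4e-06; adjusted p = 0.42 with an estimated correlation), and over all alternatives its adjusted p ranged from 1.4e-07 to 0.92. The 35 measured respiratory chain genes had a median of 0.07, which turned to -0.03 after quantile normalisation, and 0 passed in limma under either adjustment, with 4 at an unadjusted p under 0.05. Camera called this list as well (adjusted p = 0.043; adjusted p = 0.38 with an estimated correlation), but not without control array 1 (0.19) or heated array 2 (0.10). These genes are bright, and the heated arrays were brighter at the top of their range, with a 98th percentile of 8184 and 8288 against 7570 and 7716. Their 75th percentile was 487 and 482 against 508 and 509. When the tested probe sets were divided into 5 equal groups by brightness, the median log2 change was -0.03, -0.08, -0.08 and -0.07 in the dimmer 4 groups and 0.03 in the brightest. GAPDH and ACTB, used as bright reference genes, differed by 0.21 (adjusted p = 0.34) and 0.09 (0.73), and their sign turned to -0.02 and -0.14 after quantile normalisation and, for ACTB, to -0.11 after cyclic loess. In the deposited scaling the other tested probe sets of GAPDH differed by 0.31 and 0.30 and that of ACTB by 0.14, without a call.

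Among splicing factors, HNRNPA1 rose (log2 change 0.51), SRSF4, chosen after its values were seen, fell (-0.48) and 24 of 26 did not pass. Adjusted over the list alone 1 rose and 1 fell (camera adjusted p = 0.62). The 2 other tested probe sets of HNRNPA1 were not called. Among translation factors, EIF5 rose (0.64), 0 fell and 24 of 25 did not pass, with 1 rising and 1 falling when adjusted over the list alone (camera adjusted p = 0.18, or 0.023 without heated array 1). HNRNPA1, SRSF4 and EIF5 each lost the call without control array 1 (adjusted p between 0.18 and 0.30) and without control array 2 (0.052 to 0.30). SRSF4 also lost it after quantile normalisation (0.055), cyclic loess (0.063) and centring on the 75th percentile (0.084) and without _s_at and _x_at probe sets (0.056). With a replicate block, SRSF4 was not called either. HNRNPA1 lost it without heated array 1 (0.073) and EIF5 without heated array 2 (0.050, above the threshold).

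**Figure D3:**
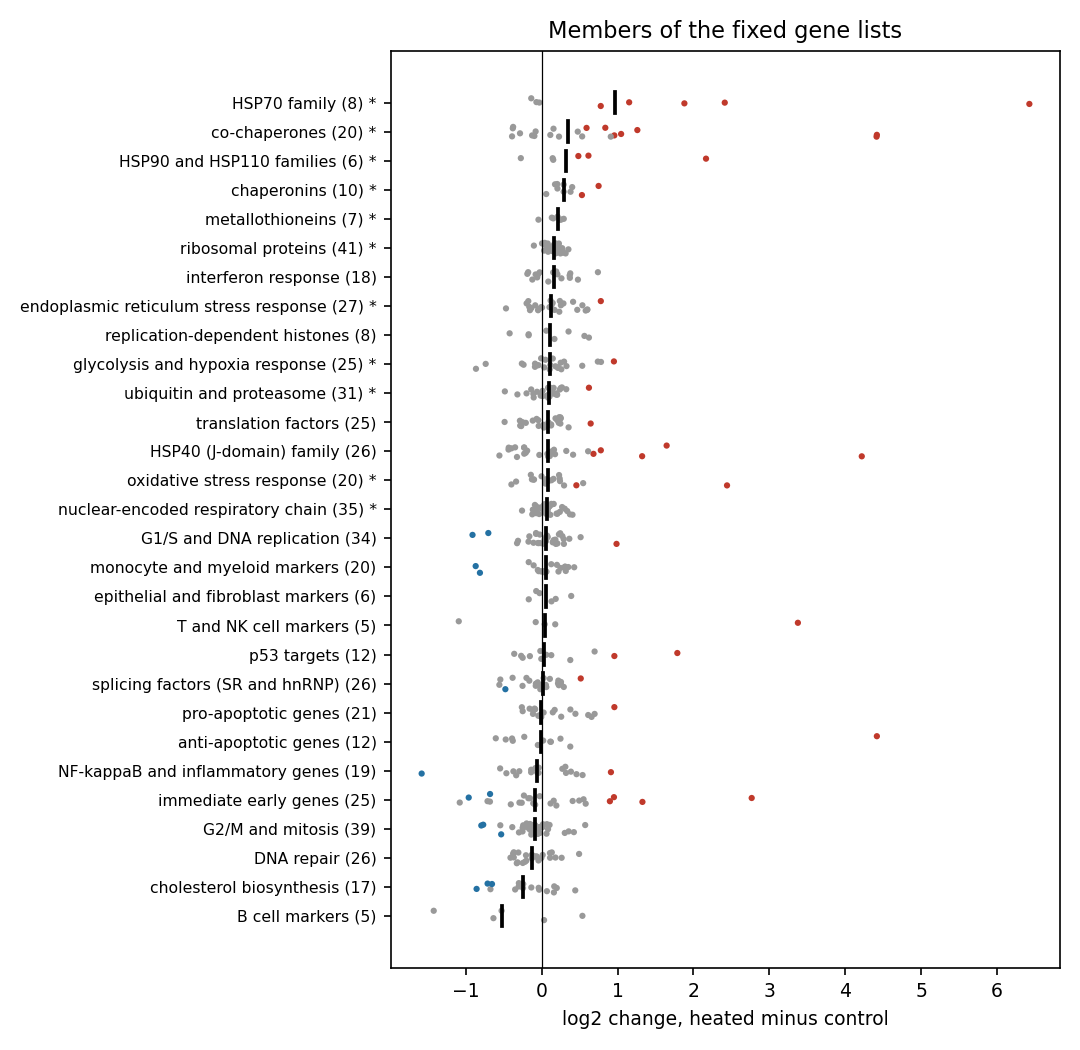
Log2 change (heated minus control) of each measured gene of the 29 tested lists, with raised genes in red, lowered genes in blue, genes not past the threshold in grey, a black bar at the list's median, the number of measured genes in parentheses and a star where camera called the list with its preset correlation. The 4 chaperone lists with a star have medians from 0.29 to 0.96, and the median of ribosomal proteins, 0.16, turned to -0.05 after quantile normalisation.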

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

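The test of ribosomal RNA in the labelled material was chosen only after its result was seen. Among the 68 control probe sets, which no comparison used, 1 of the 23 human ones was at least 1.5-fold brighter in every heated array than in every control array. AFFX-M27830_M_at, a probe set for ribosomal RNA, had a mean signal of 2561 in heated cells, from 2106 and 3015, above the 1400 and 1170 of the control cells. It is given here because it is a signal outside the main measurement above the level of the control samples. Of the control probe sets for other organisms, 0 met that rule.

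More ribosomal RNA in the labelled material of heated cells could raise this probe set. It would also raise the other 11 ribosomal RNA control probe sets, of which 8 had a higher mean in heated cells. Their median log2 difference was 0.14 (SE 0.124), with a range from -0.66 to 0.44, against 0.97 for the brighter one. The other probe sets for the RNA of the brighter one, AFFX-M27830_3_at and AFFX-M27830_5_at, differed by -0.66 and 0.08. The SE treats the 11 probe sets as independent. They share the same arrays and several target the same RNA, so it does not measure the spread between samples. The median of 0.14 argues against a general rise of the size seen in the brighter one. By this SE, however, it lies within 2 SE of 0.3, below which the test was to count no difference. A small difference and noise in 1 probe set therefore cannot be told apart, and no biological explanation was tested.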

How the results depend on the processing

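Cyclic loess, a 1.5-fold minimum beside the adjusted p, and 75th percentile centring for the lists were chosen only after the data were seen. The 553 limma calls became 199 without the filter on dim probe sets (22215 tested), 27 without the intensity trend (26 up and 1 down), 224 without _s_at and _x_at probe sets (6129 tested) and 200 to 947 without 1 array, where the lone array of a group is assumed to vary like the other group. The other alternatives apart from the replicate block gave 469 to 618. The 551 probe sets of the size rule became 1431 without the filter, 314 with the filter at the 60th percentile, 276 without _s_at and _x_at probe sets, 119 at 2-fold and 1106 to 1356 without 1 array, where fewer pairs have to pass. The 11 called lists became 0 with an estimated correlation, 5 each without the filter, after quantile normalisation and after cyclic loess, 10 with the mean of a gene's probe sets, 11 after centring on the 75th percentile and 6 to 9 without 1 array, of which 6 or 7 were among the 11 and 1 was downward (cholesterol biosynthesis, without control array 2). Of the 11, 5 were called without each array in turn. The median of ribosomal proteins reversed to -0.046 after quantile normalisation and -0.016 after cyclic loess. Of 87 called genes and probe sets named, 15 were called in every alternative that tested them and 0 reversed. Calls lost were 72 without the trend, 44 without the filter, 38 and 36 without control array 1 and 2, 9 and 7 without heated array 1 and 2, 11 after quantile normalisation, 10 after centring, 13 after cyclic loess, 2 with the smaller pseudocount, 0 with the larger one and at the 60th percentile filter, 6 of the 40 tested without _s_at and _x_at probe sets and 1 with the replicate block. Of the 55 named but not called, 4 changed sign in at least 1 alternative. Without the trend, simulated 2-fold changes were recovered in 0.448% of cases against 50.2% with it. The simulated variances followed the trend by construction, so this cannot tell whether the calls lost in the real data were true. Fewer probe sets tested and fewer arrays follow from how those alternatives are built, and for the other differences the cause was not tested.

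Arrays of the 2 groups share replicate numbers, but the labels do not say that a number marks a shared culture or day, and the deviations of same-numbered arrays had a correlation of -0.039 across probe sets. A replicate block gave 807 limma calls (377 up and 430 down), 550 of them shared, and 9 called lists, 6 of them shared, with HSP40 (adjusted p = 3.6e-05), T and NK cell markers and anti-apoptotic genes called in addition and endoplasmic reticulum stress, ubiquitin and proteasome, metallothioneins, glycolysis and hypoxia and the respiratory chain (0.067 to 0.13) not called.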

Other observations

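The ribosome biogenesis list and the genes named in this part were chosen only after results were seen, while the tests below were written before their results. Some genes that make ribosomes fell in heated cells. They include POLR1C, a subunit of RNA polymerases I and III, and NOP2 and NOP16, nucleolar proteins of the large subunit. Of 57 measured genes of a list of 72, 7 fell and 0 rose, and 48 had a lower mean in heated cells. Adjusted over the list alone 15 fell and 0 rose. The genes were POLR1C (log2 change -0.83), NOP16 (-0.71), RRP1 (-0.70), DDX10 (-0.66), PWP2 (-0.66), NOP2 (-0.65) and UTP14A (-0.62). The 1 other tested probe set of UTP14A was not called, while those of POLR1C and NOP16 were. Camera gave an adjusted p of 1.1e-06, and 0.35 with an estimated correlation. Each of the 7 lost its call without at least 1 control array. POLR1C had an adjusted p of 0.070 without control array 1, NOP16 0.12 without control array 2, and NOP2, PWP2, RRP1, DDX10 and UTP14A lost it without either (0.072 to 0.31). NOP2, PWP2 and RRP1 also lost it after quantile normalisation (0.063 to 0.090), cyclic loess (0.066 to 0.090) and centring on the 75th percentile (0.060 to 0.068). PWP2 and RRP1 lost it without heated array 1 (0.058 and 0.078) and NOP2 without heated array 2 (0.085) and without _s_at and _x_at probe sets (0.056).

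Several genes were measured by 3 or more tested probe sets that all passed the same way. Raised ones were the membrane fusion gene SNAP23 (log2 changes 1.44 to 1.69), MBNL2 (1.67 to 2.87), the thioredoxin-binding gene TXNIP (1.30 to 1.57), the inositol transporter gene SLC5A3 (1.26 to 1.65), the autophagy genes ATG5 (1.01 to 1.74) and TAX1BP1 (0.69 to 0.79), the sorting nexin gene SNX3 (0.86 to 0.92) and HSP90AA1 (0.62 to 0.83). Lowered ones were the lysosomal trafficking gene LYST (-1.25 to -0.95), the mitochondrial anchoring gene AKAP1 (-1.23 to -0.79) and INSIG1 (-1.08 to -0.83). Without the intensity trend, MBNL2 was the only 1 of these genes still called. Without the filter on dim probe sets, HSP90AA1, AKAP1 and INSIG1 were not called. Over the alternatives, the log2 change of AKAP1 ranged from -1.40 to -0.58. AKAP1 had an adjusted p of 0.16 without control array 1, and of 0.062 and 0.064 after quantile normalisation and cyclic loess.

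The small rise of ribosomal protein and respiratory chain genes can be set against a difference in scaling that depends on brightness. If scaling were the cause, the lists would lose their call after cyclic loess. They did, with a camera adjusted p of 0.9223 for ribosomal proteins and 0.4914 for the respiratory chain. Cyclic loess removes any shift that depends on brightness, whatever its cause, so this loss cannot tell scaling from an effect of heat. The respiratory chain list also lost its call without the filter on dim probe sets and with a replicate block, so its loss after cyclic loess says little. In the deposited scaling the 2 medians lay at the 58.3 and 77.6 percentiles of 10000 random lists matched on brightness, which themselves had medians of 0.16 and 0.05. After cyclic loess the 2 medians lay at the 1.93 and 53.29 percentiles, so that of ribosomal proteins was then below most matched lists. In the deposited scaling the rise of both lists thus did not stand out from that of genes of like brightness. Whether a scaling difference between the arrays or a change of all bright transcripts by heat raised them stays open and was not tested.

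The negative median of the ribosome biogenesis list was set against the same scaling difference and against a few strong members. After cyclic loess the median was -0.2139, below all 10000 matched lists, which argues against scaling as the whole cause. The camera adjusted p was then 8.5e-07 with the preset correlation, and in the deposited scaling it was 0.35 with an estimated correlation. The matched lists drew genes independently, and the list was written after results were seen. Its place below them therefore does not show how rare such a median is among genes that move together. The members that did not pass had a median of -0.1948, so lower values were not confined to the 7 called members. With 48 of 57 members lower, leaving out 7 could move the median little, so this test could hardly have come out otherwise. Lower expression of part of these genes after mild heat is a hypothesis from these 4 arrays, found and tested on the same data.

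Whether neighbours on the chromosome rise with the 77 genes raised at least 2-fold was tested as well. Their 50 tested neighbours had a mean log2 change at the 77.61 percentile of random draws matched on brightness (-0.13 to 0.06, one-sided permutation p = 0.224), and 2 of them passed upward. Neighbours that were themselves among the 77 were left out of the test and of the draws. The result therefore covers only smaller changes of neighbours and cannot show whether strongly raised genes lie next to each other.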
